A study of Macaca nemestrina with 10 samples.

How the data were processed

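RNA from the lungs of 10 pigtail macaque (Macaca nemestrina) fetuses was measured on Affymetrix Rhesus Macaque Genome Arrays, a 1-colour array with biotin-labelled RNA, with 1 array per fetus. The groups were 5 fetuses whose mothers had received Group B Streptococcus (GBS) at the choriodecidual interface and 5 whose mothers had received saline, as the treatment label of each sample states. Each fetus came from a separate pregnancy, per the series design text. Replicate numbers only name a fetus and pair nothing across groups. Fetal sex, labour, array batch and scan date are not given in the sources used here.

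The deposited values were log2 expression values, 1 per probe set and array. RMA and the affy package are named in the submitters' processing notes, without versions or settings. RMA as usually run corrects the background, makes the distributions of all arrays alike by quantile normalisation and summarises the probes of each probe set. A shift shared by most probe sets would therefore be removed before deposit, and only differences relative to the rest of the transcriptome can be read. The values lay between 1.09 and 13.9, and the medians of the arrays between 4.63 and 4.67. The probes were designed for another macaque species, so levels of different genes were not set against each other. For arrays of this kind the number of arrays limits the precision.

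The table held 52779 probe sets. The 13 Affymetrix control probe sets were left out, and 52766 were tested. Gene symbols came from the array's platform annotation, which can be old: 24956 of the tested probe sets had 1 symbol, 361 had several and 27449 had none, and only those with 1 symbol were named. No genome of the species was used here and no coordinates are given; in the gene table of the M. nemestrina assembly mMacNem.hap1, 589 array symbols and 0 array gene IDs were found, so the array's symbols were kept. For each of the 14132 gene symbols, 1 probe set stood for the gene, the one with the highest mean over the 10 arrays.

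Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate) on the log2 values as deposited, with Benjamini-Hochberg adjustment over the 52766 probe sets and a threshold of 0.05. A second count took probe sets at an unadjusted p under 0.01 and at least 1.5-fold, which controls no false discoveries. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with adjustment over the 37 lists that had at least 5 measured genes. The lists held 751 genes, of which 559 were measured and 28 stood on more than 1 list. Beside camera, each fetus's mean log2 value over a list was compared by an exact two-sided permutation test over all 252 assignments of 5 of the 10 fetuses, whose smallest possible exact p is 0.00794. The error of a list difference is the SE of the difference between group means of these per-fetus values. On data simulated for the GBS against saline comparison over 52766 probe sets, with 200 of them changed, the limma fit recovered 87% of 2-fold and 98% of 4-fold changes with 4.64% false calls. The changed probe sets were drawn at random from all those tested, so these rates hold for probe sets of typical spread. Genes that vary more between fetuses can be missed at such folds. In the real data IL1B was 4.87-fold higher in GBS at limma adjusted p = 0.455. On simulated lists over 14132 genes, a list shifted by 0.3 on the log2 scale was called and 0 of 99 unshifted lists were. Both simulations drew each probe set independently, which suits the preset correlation of 0.01 by construction. They therefore do not show how often camera calls unshifted lists when genes are correlated.

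The groups, the tests, the gene lists, the rule for naming genes and the first set of alternative settings were fixed before the data were examined. Genes were named by 3 rules. In each direction, the 10 largest differences at an adjusted p under 0.05 were to be named, and since 0 genes passed, the 10 largest among those at an unadjusted p under 0.01 with all 5 values of one group above all 5 of the other took their place. Of each list called by camera, the 3 genes with the smallest p were named. A fixed set of vessel, lung and cytokine genes was named whatever its values; VEGFA, FGF10, SHH and SFTPA1 were in that set and are not named by the annotation used here. This gave 79 genes, of which 48 had several probe sets, and for 15 of these the probe sets differed in direction. A few further genes in the text were chosen after their values were seen, and the text says so.

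The alternatives fixed at that time were a filter on dim probe sets, centring of each array on its median, quantile normalisation once more, a variance prior with an intensity trend, array weights, each fetus left out in turn, camera with an estimated correlation, fry, and 2 other ways to choose the probe set of a gene. Alternatives added after the data were seen were the 3'/5' signal ratio of the actin and GAPDH control probe sets as a covariate, removal of each array's intensity-dependent deviation from the mean array (lowess, span 0.3), and the repeated quantile normalisation for the gene lists. 100 of the 126 possible splits of the arrays into 5 and 5 were fitted again to see how often other groupings gave results as large.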

Results

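Gene expression was measured in the lungs of 10 pigtail macaque fetuses. The mothers had received Group B Streptococcus (GBS), a bacterium that can colonise the genital tract and infect newborns, or saline, placed between the fetal membranes and the wall of the uterus. Inoculation took place between day 118 and day 125 of a gestation of 172 days, and the lungs were collected within a week of it whether or not labour had started. There were 5 fetuses in each group, with 1 array per fetus. Pairs of arrays correlated at r = 0.976 to 0.990 across probe sets, which are not independent replicates. The comparison of the groups asks how bacterial exposure at the membranes alters expression in the fetal lung, and the series title names angiogenesis and morphogenesis.

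In the lungs of GBS-exposed fetuses, genes of macrophages, antigen presentation, neutrophils and cytokines were higher as groups. Genes of vessels, smooth muscle, elastic fibres and lung morphogenesis were lower as groups. The macrophage and monocyte list differed most, with a mean 0.94 higher on the log2 scale (SE 0.34, n = 5 and 5), and among the lower lists the smooth muscle and pericyte list differed most, by -0.37 (SE 0.17). By limma's camera at its preset correlation, 17 of 37 lists shifted at an adjusted p under 0.05, 9 higher and 8 lower. With an estimated correlation camera called 0 lists, the smallest value being adjusted p = 0.463 with an estimated correlation. The adjustment gave that same value to many lists, so it does not rank them. Unadjusted, camera p with an estimated correlation was under 0.05 for 3 lists: heat shock (0.0151), endothelium (0.0378) and angiogenesis (0.0400). The estimated correlation was 0.52 for the macrophage list and 0.062 for the angiogenesis list, against the preset 0.01. limma's fry also called 0 lists (smallest adjusted p = 0.0908), with 5 lists at an unadjusted p under 0.05. The exact permutation test of per-fetus list means gave 8 lists at an unadjusted exact p under 0.05 and 0 after adjustment over the lists (smallest adjusted exact p = 0.176).

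**Figure D1:**
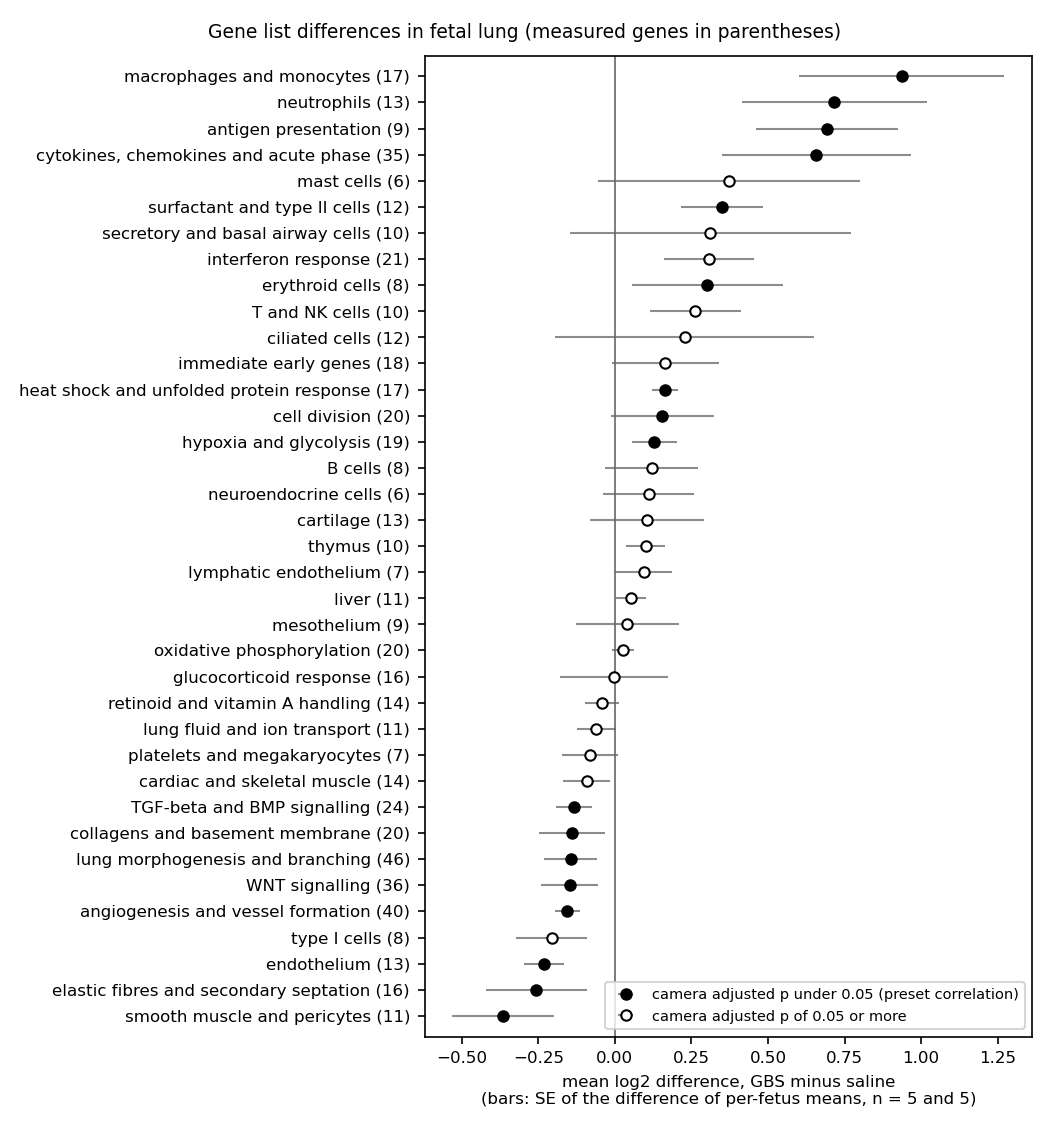
Mean log2 difference, GBS minus saline, of each of the 37 gene lists, with the number of measured genes in parentheses and bars for the SE of the difference between per-fetus means (n = 5 and 5). Filled points are the 17 lists called by camera at its preset correlation, 9 above 0 and 8 below 0.

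Macrophage and monocyte markers were higher in GBS for 15 of 17 measured genes, 13 of them at an unadjusted p under 0.05. The list mean was 7.41 ± 0.61 in GBS and 6.48 ± 0.43 in saline (SD, n = 5), and limma's camera gave adjusted p = 6.22e-08, against adjusted p = 0.463 with an estimated correlation. CD74, the chaperone of MHC class II molecules, was 1.66 higher (SE 0.44), and CTSS, a lysosomal protease of antigen-presenting cells, 1.30 higher (SE 0.39). CD68, a lysosomal protein of macrophages, was 1.10 higher (SE 0.36) on the probe set used, while its other probe set had the opposite direction. Of the 17 genes, 0 passed over all genes tested and 10 passed, all higher, adjusted over the list alone. The exact permutation test of the per-fetus means gave p = 0.0317.

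Genes of antigen presentation were higher in 9 of 9 measured cases, with a list mean of 8.90 ± 0.40 in GBS and 8.21 ± 0.33 in saline (SD, n = 5). limma's camera gave adjusted p = 5.19e-06, against adjusted p = 0.463 with an estimated correlation, and the exact permutation p was 0.0238. MAMU-DRA, the alpha chain of an MHC class II molecule, was 1.48 higher (SE 0.36), and PSMB8, a subunit of the immunoproteasome, 0.86 higher (SE 0.28). Over all genes tested 0 of the 9 passed, and 4 passed adjusted over the list alone. CD74 stands on both this list and the macrophage list.

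Cytokine, chemokine and acute phase genes were higher for 32 of 35 measured members, 12 of them at an unadjusted p under 0.05, and 1 of the 3 lower members reached the same level. The list mean was 6.52 ± 0.63 in GBS and 5.87 ± 0.29 in saline (SD, n = 5), a difference of 0.66 (SE 0.31). limma's camera gave adjusted p = 7.92e-07, against adjusted p = 0.463 with an estimated correlation, and the exact permutation p was 0.0476. PTX3, a soluble pattern recognition protein, was 0.95 higher (SE 0.30), and TNFAIP3, a feedback inhibitor of NF-kB, 0.72 higher (SE 0.25), with 1 of its 5 probe sets in the opposite direction. The neutrophil attractant CXCL8 was 1.93 higher (SE 0.71) and IL1B 2.28 higher (SE 1.02). IL1R2, a decoy receptor for interleukin 1, was lower by -0.36 (SE 0.10), but 3 of its 4 probe sets had the opposite direction. IL6 was 0.61 higher (SE 0.61) and TNF 0.0072 higher (SE 0.081), both within the spread. IL6 was 0.17 without GBS replicate 3 and 0.96 without GBS replicate 1, and TNF turned below 0 with other normalisations. Over all genes and adjusted over the list alone, 0 of the 35 passed. Within the GBS group replicates 3 and 4 had list means of 7.32 and 7.08 and the others 6.02 to 6.10, and in the saline group replicate 4 had 6.37 and the others 5.71 to 5.79.

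Neutrophil markers were higher for 11 of 13 measured genes, 5 of them at an unadjusted p under 0.05, with a list difference of 0.72 (SE 0.30, n = 5 and 5). limma's camera gave adjusted p = 8.66e-05, against adjusted p = 0.463 with an estimated correlation, and the exact permutation p was 0.0238. CSF3R, the receptor for granulocyte colony-stimulating factor, was 0.62 higher (SE 0.24), and the antimicrobial peptide gene CAMP 0.52 higher (SE 0.21), or 0.35 without GBS replicate 3. LCN2, an iron-sequestering protein of neutrophil granules and inflamed epithelium, was 1.97 higher (SE 0.79), but 3 of its 4 probe sets had the opposite direction. Over all genes and adjusted over the list alone, 0 of the 13 passed. Without GBS replicate 3 the list difference was 0.47.

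Genes of angiogenesis and vessel formation were lower for 29 of 40 measured members, 12 of them at an unadjusted p under 0.05, with 1 of the 11 higher members at the same level. Among all probe sets with a mean level of 7.02 to 8.15, the range that holds this list's mean, 32.4% were higher in GBS. Most probe sets of that level were therefore lower as well. The list mean was 7.29 ± 0.076 in GBS and 7.45 ± 0.048 in saline (SD, n = 5), a difference of -0.16 (SE 0.040), and 4 of 5 GBS fetuses lay below every saline fetus. limma's camera gave adjusted p = 7.83e-04, against adjusted p = 0.463 with an estimated correlation, and the exact permutation p was 0.0238. The endothelial transcription factor ERG was lower by -0.38 (SE 0.094), SOX17, a transcription factor of arterial endothelium, by -0.52 (SE 0.16), and RASIP1, needed for the opening of vessel lumens, by -0.32 (SE 0.089). ANGPT1, the ligand of the endothelial receptor TEK, was lower by -0.68 (SE 0.20), with 1 of its 4 probe sets in the opposite direction. TEK itself was lower by -0.21 (SE 0.10), again with 1 of 2 probe sets in the opposite direction. KDR, a receptor for vascular endothelial growth factor, was 0.28 higher (SE 0.13) at levels of 3.72 and 3.43, which lie below the array medians. Over all genes and adjusted over the list alone, 0 of the 40 passed. The theme came from the title of the series, which describes these same fetuses, so the list is not independent evidence of the direction. With the mean of all probe sets of a gene the difference was -0.097.

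Endothelial marker genes were lower for 11 of 13 measured members, 5 of them at an unadjusted p under 0.05, and 7 of the 13 stand on other lists as well. The list mean lies in the range of level of 8.15 to 13.6, where 38.3% of all probe sets were higher in GBS. The list difference was -0.23 (SE 0.067), with 5 of 5 GBS fetuses below every saline fetus (exact permutation p = 0.00794, the smallest possible). limma's camera gave adjusted p = 0.00108, against adjusted p = 0.463 with an estimated correlation. The junction proteins PECAM1 and CDH5 were lower by -0.29 (SE 0.11) and -0.28 (SE 0.11), and RAMP2, part of the adrenomedullin receptor, by -0.34 (SE 0.12). Over all genes 0 passed, and 1, ERG, passed adjusted over the list alone.

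**Figure D2:**
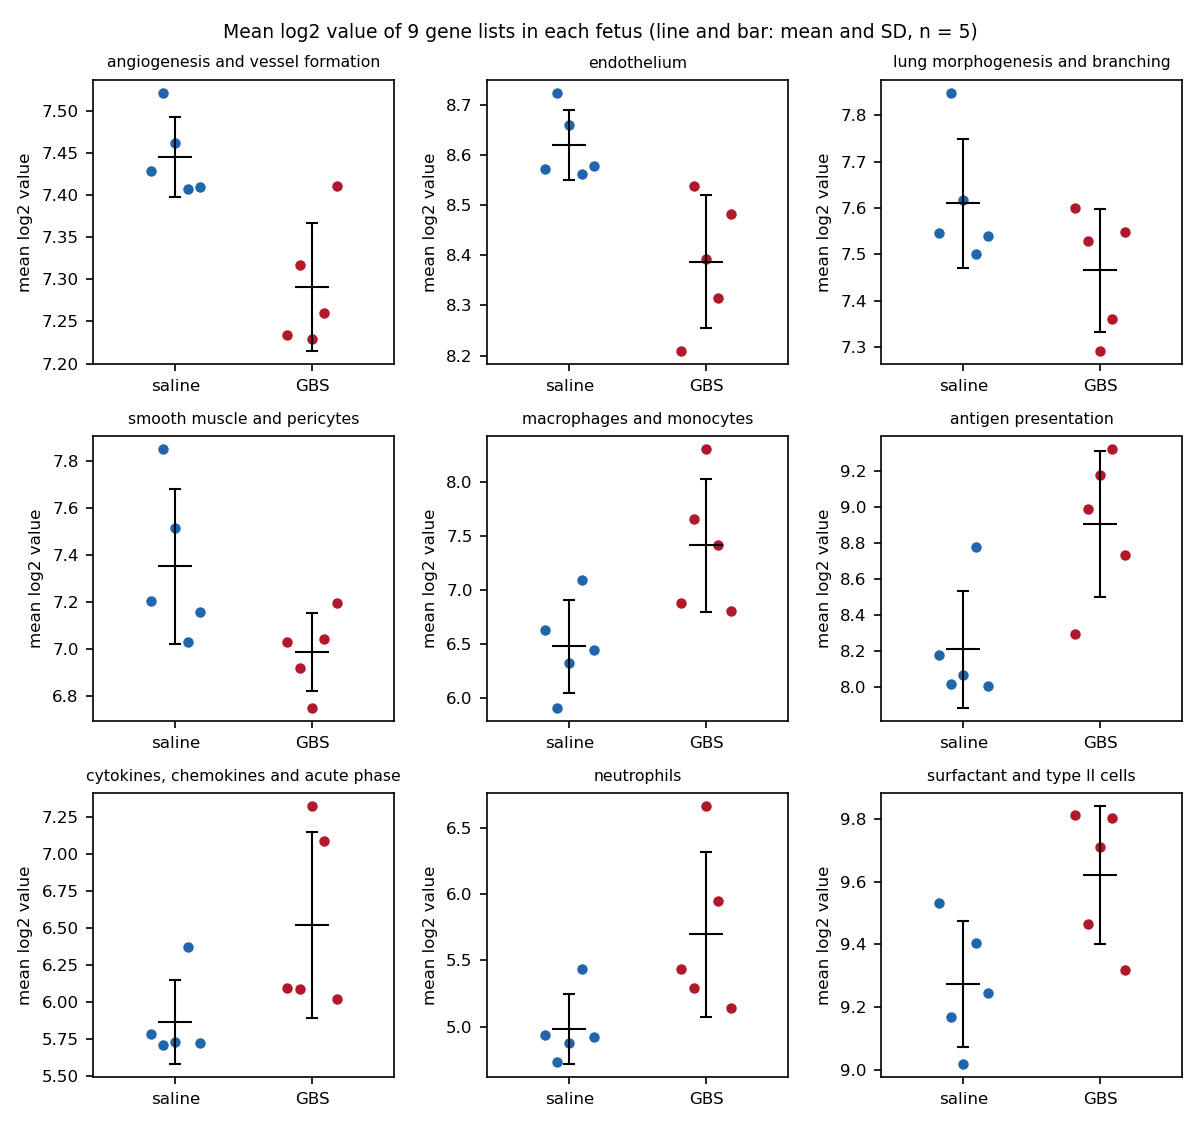
Mean log2 value over 9 gene lists in each fetus, saline in blue and GBS in red, with the group mean and SD (n = 5) in black. The 5 GBS fetuses lie below all saline fetuses for the endothelium list, while the groups overlap for each of the other 8 lists.

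Genes of lung morphogenesis and branching were lower for 33 of 46 measured members, 8 of them at an unadjusted p under 0.05. The list mean lies in the range of level of 7.02 to 8.15, where 32.4% of all probe sets were higher in GBS. The list difference was -0.14 (SE 0.086, n = 5 and 5), with limma's camera at adjusted p = 0.00617, against adjusted p = 0.463 with an estimated correlation, and an exact permutation p of 0.167. The T-box factors TBX2 and TBX3, which act in lung mesenchyme, were lower by -0.65 (SE 0.16) and -0.47 (SE 0.14), the latter with 1 of 4 probe sets in the opposite direction. SPRY1, an inhibitor of fibroblast growth factor signalling, was lower by -0.19 (SE 0.065) with no overlap between the groups. The epithelial factor NKX2-1 was lower by -0.14 (SE 0.17) and the mesenchymal factor FOXF1 by -0.11 (SE 0.30), both within the spread; NKX2-1 was -0.24 to -0.045 with a fetus left out and turned above 0 with the control 3'/5' ratio as a covariate, and FOXF1 without saline replicate 3 or 5. Over all genes and adjusted over the list alone, 0 of the 46 passed. This theme too came from the series title and is not independent evidence of its direction. The call ended without saline replicate 2 (difference -0.085, limma camera adjusted p = 0.0813) and with the control 3'/5' ratio as a covariate (-0.084, limma camera adjusted p = 0.0709).

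Smooth muscle and pericyte markers were lower for 11 of 11 measured genes, 6 of them at an unadjusted p under 0.05. The list mean lies in the range of level of 7.02 to 8.15, where 32.4% of all probe sets were higher in GBS. limma's camera gave adjusted p = 3.75e-04, against adjusted p = 0.463 with an estimated correlation, and the exact permutation p was 0.0556. MYH11, the smooth muscle myosin heavy chain, was lower by -0.58 (SE 0.20), the actin-binding protein SYNPO2 by -0.55 (SE 0.17) and the adhesion molecule MCAM by -0.38 (SE 0.16). Without saline replicate 2 MYH11 was lower by -0.37. MYH11 had 1 of 4 and SYNPO2 1 of 2 probe sets in the opposite direction. Over all genes and adjusted over the list alone, 0 of the 11 passed. The list difference was -0.24 without saline replicate 2, whose list mean of 7.85 was the highest, and also -0.24 with the mean of all probe sets of a gene.

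Elastic fibre and septation genes were lower for 15 of 16 measured members, by -0.26 on average (SE 0.17), and collagen and basement membrane genes for 17 of 20, by -0.14 (SE 0.11). At an unadjusted p under 0.05, 4 and 3 of these were lower, and over all genes or adjusted over the list alone 0 passed. Both list means lie in the range of level of 8.15 to 13.6, where 38.3% of all probe sets were higher in GBS. limma's camera gave adjusted p = 0.00282 for elastic fibres (adjusted p = 0.518 with an estimated correlation) and adjusted p = 0.0358 for collagens (adjusted p = 0.525 with an estimated correlation). The exact permutation p was 0.159 and 0.270. FBLN5, which organises elastin, was lower by -0.47 (SE 0.18), or -0.30 without saline replicate 2, LTBP2 by -0.53 (SE 0.21) and EFEMP1 by -0.25 (SE 0.10). The basement membrane gene NID1 was lower by -0.44 (SE 0.12) with no overlap between groups, and the collagen chains COL6A3 by -0.31 (SE 0.11) and COL5A2 by -0.33 (SE 0.15) with 2 of 4 probe sets in the opposite direction. The elastic fibre difference was -0.13 without saline replicate 2, and its call ended with the control 3'/5' ratio as a covariate (-0.16, limma camera adjusted p = 0.0510). The collagen call ended with that covariate, with the filter on dim genes, with removal of the intensity-dependent deviation, and without GBS replicate 2, 3 or 4 or saline replicate 2 or 3 (limma camera adjusted p = 0.0530 to 0.244 among the latter). The collagen difference was -0.059 without saline replicate 2 and -0.061 with the covariate, and -0.14 to -0.094 in the other fits that lost the call.

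WNT signalling genes were lower for 28 of 36 measured members, 7 of them at an unadjusted p under 0.05, and TGF-beta and BMP signalling genes for 18 of 24, 3 of them at that level. The WNT list mean lies in the range of level of 6.12 to 7.02, where 38.0% of all probe sets were higher in GBS. For the TGF-beta and BMP list the range is 7.02 to 8.15, where 32.4% were higher. The list differences were -0.15 (SE 0.094) and -0.13 (SE 0.059). limma's camera gave adjusted p = 0.00722 for WNT and 0.0472 for TGF-beta and BMP, against adjusted p = 0.463 with an estimated correlation for both, and the exact permutation p was 0.151 and 0.0635. The ligand WNT3 was lower by -0.70 (SE 0.16) and was the only WNT list member to pass adjusted over the list alone; over all genes 0 passed on either list, and on the TGF-beta and BMP list 0 passed alone. WNT7A was lower by -0.32 (SE 0.11) and the receptor FZD4 by -0.31 (SE 0.086), the latter with 1 of 2 probe sets in the opposite direction. The endothelial TGF-beta receptor ACVRL1 was lower by -0.42 (SE 0.16), or -0.28 without GBS replicate 1, the signal transducer SMAD3 by -0.36 (SE 0.14) and the co-receptor TGFBR3 by -0.27 (SE 0.11). With the control 3'/5' ratio as a covariate the WNT difference was -0.077. The TGF-beta and BMP call ended with that covariate, with the filter on dim genes, after repeated quantile normalisation or removal of the intensity-dependent deviation, and without GBS replicate 3, 4 or 5 or saline replicate 3 or 5 (limma camera adjusted p = 0.0598 to 0.171 among the latter), while the difference in these fits was -0.15 to -0.091.

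Surfactant and type II cell genes were higher for 11 of 12 measured members, with a list difference of 0.35 (SE 0.13, n = 5 and 5) and a median of 0.16. SLPI and DMBT1 carried much of the mean, and the other 10 genes had a mean 0.16 higher (SE 0.15). SFTPB was 0.0030 higher (SE 0.096) and SFTPC 0.088 higher (SE 0.15), and both turned below 0 in some settings. Their means of 13.1 and 13.5 in GBS lie near the array maxima of 13.7 to 13.9, which limits what their differences show. SLPI, a protease inhibitor, was 1.21 higher (SE 0.45), with its highest value, 8.68, in GBS replicate 1. The phosphate transporter SLC34A2 was 0.46 higher (SE 0.18). CTSH, a protease that processes surfactant protein, was 0.27 higher (SE 0.16), or 0.14 without GBS replicate 3. Of the 12 genes, 2 reached an unadjusted p under 0.05, and 0 passed over all genes or adjusted over the list alone. limma's camera gave adjusted p = 0.0358, against adjusted p = 0.463 with an estimated correlation, and the exact permutation p was 0.0397. The camera call ended with the control 3'/5' ratio as a covariate, after removal of the intensity-dependent deviation, with the probe set of largest variance, and without GBS replicate 3 or 4 or saline replicate 2, 3 or 5 (limma camera adjusted p = 0.0530 to 0.150 among the latter). In the first 3 of these settings the list difference was 0.38, 0.37 and 0.37, and in the fits without a fetus 0.28 to 0.34. Type I cell markers were lower for 7 of 8 genes, by -0.21 (SE 0.12), with limma's camera at adjusted p = 0.133. Their list mean lies in the range of level of 8.15 to 13.6, where 38.3% of all probe sets were higher in GBS. The type I list passed without saline replicate 2 (-0.28, limma camera adjusted p = 0.0402) and with the control 3'/5' ratio as a covariate (-0.31, limma camera adjusted p = 0.0115). With an estimated correlation it had adjusted p = 0.463 in the fit of all fetuses and adjusted p = 0.272 with the covariate.

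Heat shock and unfolded protein response genes were higher for 14 of 17 measured members, by 0.16 on average (SE 0.043), and 4 of 5 GBS fetuses lay above every saline fetus. limma's camera gave adjusted p = 0.0119, against adjusted p = 0.463 with an estimated correlation (unadjusted camera p = 0.0151). The exact permutation p was 0.0159. The members with the smallest p were stress transcription factors: ATF3 was 0.82 higher (SE 0.20), DDIT3 0.38 higher (SE 0.13) and ATF4 0.18 higher (SE 0.073). At an unadjusted p under 0.05, 3 were higher; over all genes 0 passed, and 1, ATF3, passed adjusted over the list alone. With the probe set of largest variance the list difference was 0.30.

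Hypoxia and glycolysis genes were higher for 14 of 19 measured members, by 0.13 on average (SE 0.073), and limma's camera gave adjusted p = 0.0480, against adjusted p = 0.463 with an estimated correlation (exact permutation p = 0.135). The glycolytic enzymes LDHA and ALDOA were 0.33 (SE 0.14) and 0.22 (SE 0.091) higher. PFKFB3, which makes an activator of glycolysis, was lower by -0.74 (SE 0.17) and was the only member to pass adjusted over the list alone. The call ended with array weights, with the control 3'/5' ratio as a covariate, and without GBS replicate 1, 2 or 3 or saline replicate 2, 3 or 5 (limma camera adjusted p = 0.0528 to 0.192 among the latter), while the difference in these fits was 0.092 to 0.14. Over all genes 0 of the 19 passed.

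Cell division genes were higher for 18 of 20 measured members, by 0.15 on average (SE 0.17), and erythroid genes for 8 of 8, by 0.30 (SE 0.25). limma's camera gave adjusted p = 0.0149 for cell division (adjusted p = 0.572 with an estimated correlation) and adjusted p = 0.0472 for erythroid genes (adjusted p = 0.525 with an estimated correlation), and the exact permutation p was 0.325 and 0.254. The mitotic kinase AURKB was 0.16 higher (SE 0.063) without overlap between groups, the replication clamp PCNA 0.25 higher (SE 0.11) and TYMS, which makes thymidylate, 0.49 higher (SE 0.26), or 0.31 without GBS replicate 4. Fetal globin HBG2 was 0.52 higher (SE 0.21), EPB42 0.15 higher (SE 0.12) and ALAS2, the first enzyme of erythroid haem synthesis, 0.50 higher (SE 0.41), with 1 of 2 probe sets of ALAS2 in the opposite direction. HBG2, at 13.4 in GBS and up to 13.7 in saline, lies near the array maxima, which limits what its difference shows. Without saline replicate 1 ALAS2 was 0.96 and EPB42 0.24 higher. On each list 1 gene reached an unadjusted p under 0.05 and 0 passed over all genes or adjusted over the list alone. The cell division call ended without GBS replicate 4 or saline replicate 1 or 3 (limma camera adjusted p = 0.0506 to 0.238) and with the probe set of largest variance; the difference was 0.058 without saline replicate 3, 0.068 without GBS replicate 4 and 0.28 without saline replicate 2. The erythroid call ended without any fetus other than GBS replicate 3 or saline replicate 1 (limma camera adjusted p = 0.0502 to 0.178 for the 8 others), after repeated quantile normalisation or removal of the intensity-dependent deviation, with the 3'/5' covariate and with both other ways to choose probe sets; the difference was 0.19 without saline replicate 2, 0.21 to 0.32 in the other fits that lost the call, and 0.52 without saline replicate 1.

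No single gene passed. limma called 0 of 52766 probe sets at an adjusted p under 0.05 (smallest adjusted p = 0.337), and 5739 had an unadjusted p under 0.05, 2554 higher and 3185 lower, where chance alone gives 2638. At an unadjusted p under 0.01 and at least 1.5-fold there were 269 probe sets, 118 higher and 151 lower in GBS; with each array centred on its median the split was 88 higher and 198 lower. This count was 159 without GBS replicate 4, 168 without GBS replicate 3, 172 without saline replicate 2, 443 without GBS replicate 1, 512 without GBS replicate 5 and 608 without saline replicate 4. Groups did not overlap for 290 of 14132 genes, 115 higher and 175 lower, against the 0.794% of genes, or 112, that chance gives. The values 2638 and 112 are expected counts, whose spread over other groupings was not computed, so no excess over chance was tested. The count at an unadjusted p under 0.01 and at least 1.5-fold ran from 18 to 654 over other splits of the arrays.

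The genes with the largest differences among those without overlap at an unadjusted p under 0.01 are given here by size, since none passed. On the higher side CH25H, the enzyme that makes 25-hydroxycholesterol, was 6.34 ± 0.56 in GBS and 4.85 ± 0.25 in saline (SD, n = 5), 1.49 higher (SE 0.24; limma adjusted p = 0.337). PTX3, named with the cytokines, followed, then RNASE6, an antimicrobial ribonuclease, 0.90 higher with its other probe set in the opposite direction, SMPDL3A, a phosphodiesterase, 0.83 higher, and SYTL3 0.78 higher. The fatty acid binding protein FABP4 was 0.77 higher, adenosine deaminase 2 (ADA2) 0.62, the cell cycle protein CKS2 0.61, the beta-glucan receptor CLEC7A 0.61 and the hyaluronan receptor CD44 0.52. On the lower side PROCA1 differed by -0.95 (SE 0.26), LOC695935 by -0.79, SGIP1, an endocytosis protein, by -0.75, ANGPT1 by -0.68 and the muscle transcription factor MYF6 by -0.67. CPT1A, which carries fatty acids into mitochondrial oxidation, was lower by -0.66 (SE 0.12) with its other probe set in the opposite direction, and the exocyst subunit EXOC2 by -0.64. PLCD4 differed by -0.58, UGGT2, a folding sensor of the endoplasmic reticulum, by -0.57 with 1 of 4 probe sets in the opposite direction, and ZNF596 by -0.57. The limma adjusted p of these 20 genes lay between 0.337 and 0.398, so 0 passed.

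**Figure D3:**
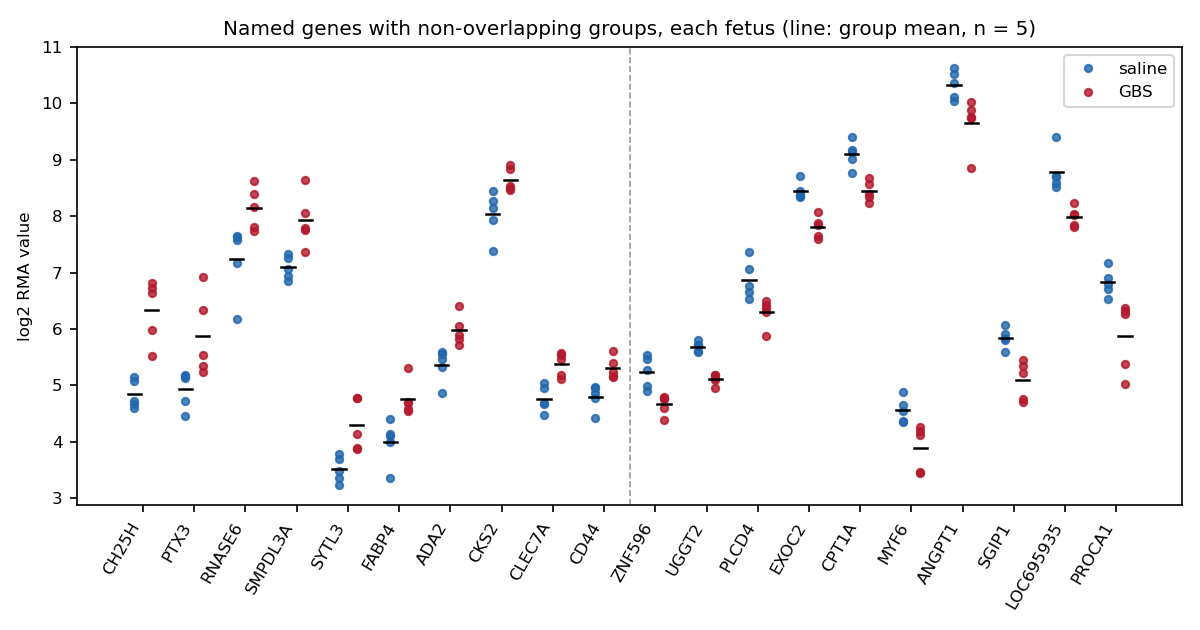
Log2 RMA value of each fetus for the 20 genes with the largest differences among those whose groups do not overlap at an unadjusted p under 0.01, saline in blue and GBS in red, with lines at the group means (n = 5). The difference between group means is largest for CH25H among the higher genes, 6.34 against 4.85, and for PROCA1 among the lower, 5.88 against 6.83.

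Among the 20 lists that camera did not call, T and NK cell markers were higher by 0.26 (SE 0.15), B cell markers by 0.12 (SE 0.15), thymus markers by 0.10 (SE 0.063) and interferon response genes by 0.31 (SE 0.15), the last higher for 15 of 21 genes. Their limma camera adjusted p was 0.245, 0.0636, 0.0893 and 0.0679. Mast cell markers had a mean 0.37 higher (SE 0.43) but a median of -0.040 and a test pointing down, and the mean was 0.18 without saline replicate 2 and 0.69 without saline replicate 4. Ciliated, secretory and basal, neuroendocrine and cartilage lists were higher by 0.23, 0.31, 0.11 and 0.11 with SEs of 0.42, 0.46, 0.15 and 0.19. These 4 lists turned below 0 without GBS replicate 1, at -0.15, -0.083, -0.0080 and -0.061. Lymphatic endothelium was 0.094 higher (SE 0.094) with a median of -0.010, mesothelium 0.041 (SE 0.17) and liver 0.053 (SE 0.049). Immediate early genes were 0.16 higher (SE 0.18) and oxidative phosphorylation 0.027 higher (SE 0.035). The glucocorticoid response was lower by -0.0030 (SE 0.18), lung fluid and ion transport by -0.061 (SE 0.063). Platelets, cardiac and skeletal muscle, and retinoid handling had means of -0.080, -0.093 and -0.043 with a test pointing up. The limma camera adjusted p of all 20 lay between 0.0594 and 0.988. With a fetus left out, 18 of the 20 differences moved by more than 1.5 times in some fit. Some passed when a fetus was left out: ciliated cells without GBS replicate 3, 4 or 5 or saline replicate 1, 2 or 4 (limma camera adjusted p = 0.00615 to 0.0492), B cells without GBS replicate 1 or saline replicate 3 or 4 (0.0106 to 0.0429), the interferon response without GBS replicate 1 or 3 or saline replicate 4 (0.00747 to 0.0358), secretory and basal cells without GBS replicate 4 (0.0404), thymus without GBS replicate 2 (0.0461) and immediate early genes without GBS replicate 5 (0.0486). Other settings also gave calls. With the control 3'/5' ratio as a covariate ciliated cells passed at a difference of 0.59 (limma camera adjusted p = 1.86e-05), secretory and basal cells at 0.73 (0.00400) and cartilage at 0.28 (0.00252). In that fit these 3 had adjusted p = 0.453, 0.272 and 0.403 with an estimated correlation. The interferon response passed in 7 settings, with differences of 0.28 to 0.49: the filter on dim genes, centred arrays, repeated quantile normalisation, array weights, removal of the intensity-dependent deviation, and both other ways to choose probe sets (limma camera adjusted p = 0.00523 to 0.0431), against adjusted p = 0.525 with an estimated correlation in the fit of all fetuses. Ciliated cells also passed with the filter on dim genes and with centred arrays (0.0268 and 0.0343), and B cells with centred arrays and array weights (0.0431 and 0.0387), against adjusted p = 0.617 and 0.525 with an estimated correlation. All these passes are at the preset correlation, and the estimated correlation was run only in the fit of all fetuses and with the covariate, where it called 0 lists.

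**Figure D4:**
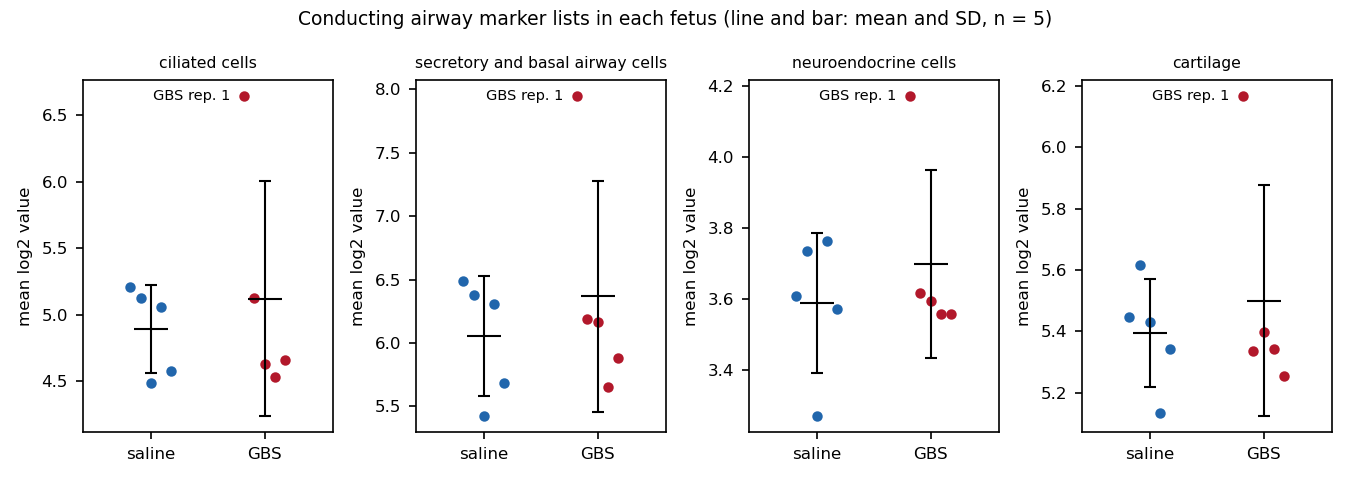
Mean log2 value of the ciliated, secretory and basal, neuroendocrine and cartilage marker lists in each fetus, saline in blue and GBS in red, with group mean and SD (n = 5) in black. GBS replicate 1 is the highest of the 10 fetuses on each of the 4 lists, at 6.65, 7.95, 4.17 and 6.17.

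Summaries of whole arrays differed between the groups only in part. The log2 3'/5' signal ratio of the actin and GAPDH controls, which grows as RNA degrades, was 1.64 ± 0.38 in GBS and 1.94 ± 0.37 in saline (SD, n = 5; exact permutation p = 0.262). Positions on the first principal component differed between the groups (exact permutation p = 0.0317). That component summarises expression over all probe sets and is no measure of array quality. Probe sets of low mean level leaned toward GBS and those of high level toward saline: over 10 equal bins of mean level, the median difference was 0.048 in the fourth and -0.080 in the ninth. In bins 8, 9 and 10, 38.0%, 32.4% and 38.3% of probe sets were higher in GBS, so most were lower. Counts of lower members on lists of bright genes have to be read beside these shares. Lists in the range of the bins with a median below 0 went both ways: the vessel formation and collagen lists, with means of 7.45 and 9.71 in saline, were lower, and the antigen presentation, heat shock and type II lists, with means of 8.21, 8.29 and 9.27, were higher.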

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

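The tests of RNA integrity in the vessel pattern and in GBS replicate 1, of intensity-dependent deviation and of immune cell dilution were chosen only after the results were seen.

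Of 232 groups of 5 tested with Dixon's gap ratio, 26 held a fetus whose gap exceeded the critical value, where chance gives about 12. The most were 7 in saline replicate 2, 6 in saline replicate 4 and 4 in GBS replicate 1. The others lay in saline replicate 1 and GBS replicates 2, 3 and 5. The lists and genes tested overlap, and whether the outlying values gather in some fetuses was not tested. In saline replicate 4, inflammatory lists stood above the other saline fetuses: cytokines at 6.37 against 5.71 to 5.79 (gap ratio 0.881), antigen presentation at 8.78 against 8.01 to 8.18 (0.775) and neutrophils at 5.43 against 4.73 to 4.93 (0.7102). The same fetus had IL1B at 8.23 against 4.61 to 4.98 (0.899), and low IL1R2 (7.26, ratio 0.727) and WNT7A (5.20, ratio 0.714). Saline replicate 2 had high MYH11 (10.4 against 9.24 to 9.43, ratio 0.832), FBLN5 (10.3, ratio 0.755), LOC695935 (9.41, ratio 0.779) and TYMS (6.47, ratio 0.719). It had low SFTPC (12.8 against 13.5 to 13.7, ratio 0.853), LDHA (9.89, ratio 0.713) and type I markers (8.64 against 8.94 to 9.04, ratio 0.743). Saline replicate 1 had high ALAS2 (9.01 against 6.52 to 6.91, ratio 0.841), EPB42 (3.77, ratio 0.731) and EXOC2 (8.72, ratio 0.719). In the GBS group replicate 5 was high in platelet markers (5.02, ratio 0.756), LTBP2 (9.26, ratio 0.786) and SMAD3 (9.13, ratio 0.716). GBS replicate 3 was high in mesothelial markers (5.61, ratio 0.747) and low in ANGPT1 (8.86 against 9.75 to 10.03, ratio 0.759), and GBS replicate 2 was high in FABP4 (5.32, ratio 0.792).

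GBS replicate 1 stood above the other 4 GBS fetuses in ciliated (6.65 against 4.53 to 5.12, ratio 0.720), secretory and basal (7.95 against 5.65 to 6.19, ratio 0.764), neuroendocrine (4.17 against 3.56 to 3.62, ratio 0.903) and cartilage markers (6.17 against 5.25 to 5.40, ratio 0.845). The log2 3'/5' control ratio of this array was 2.19, above the 1.25 to 1.76 of the other GBS arrays and below the 2.54 of saline replicate 2. Each list was fitted on that ratio over the other 9 arrays. In this fetus each lay at least 3.37 SE of the prediction above its predicted value. That argues against a difference in RNA integrity as the whole cause. The fetus and the lists were picked because they stood out, so the distances in SE may be inflated by that choice. The fit also assumes a straight line. The median of 26 further airway epithelium genes on none of the fixed lists was 5.64 in this fetus and 4.82 to 5.10 in the others, 0.53 above the highest of them, which is consistent with more conducting airway in the sampled piece of lung. That remains a hypothesis, and no biological explanation tied to the inoculation was tested.

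The angiogenesis list was lower in GBS while immune lists were higher. With each array's intensity-dependent deviation removed the list stayed lower by -0.12 (exact permutation p = 0.0159). With the control 3'/5' ratio as a covariate it stayed lower by -0.16 (SE 0.047), with limma camera adjusted p = 8.92e-05 at the preset correlation. The covariate fit gave adjusted p = 0.272 with an estimated correlation, where the list was not called without the covariate either. Neither adjustment took the difference away. The ratio rests on actin and GAPDH alone, and both checks were chosen after the result was seen. RNA integrity and intensity-dependent deviation are therefore not excluded as causes. Immune cells diluting all resident cells alike may still contribute. The difference between groups was 0.39 larger for type II cell genes, without SLPI and DMBT1, than for endothelial genes (exact permutation p = 0.0635). With all 12 type II genes it was 0.58 larger (exact permutation p = 0.0397). These values leave open whether resident cell types moved apart. An effect of the inoculation on lung vessels also stays open, as a hypothesis.

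Other splits of the arrays bear on how far chance can be excluded. limma called 0 probe sets in the real grouping, a count that 100 of 100 splits, the real one included, reach by definition, and the highest other split called 42. For the 269 probe sets at an unadjusted p under 0.01 and at least 1.5-fold, 5 of 100 splits gave as many, and the highest other gave 654. For the 17 shifted lists, 9 of 100 splits gave as many, and the highest other gave 19. Chance was excluded for none of these counts. The split with 654 and 42 differs from the real one by an exchange of saline replicate 4 with GBS replicate 1. It was picked as the highest, and a structure of the samples behind it was not tested. Another split, with GBS replicates 3 and 5 beside saline replicates 1, 2 and 3, called 19 probe sets.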

How the results depend on the processing

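The covariate from the control 3'/5' ratio, the removal of intensity-dependent deviation and the repeated quantile normalisation of the lists were chosen after the data were seen. limma called 0 probe sets in every setting run. The 17 called lists kept their direction in every setting, 16 of them being testable with the filter on dim genes, and 10 kept their call in each fit that left out a fetus; 10 kept it with the 3'/5' covariate, 13 with the deviation removed and 17 with arrays centred. Of the 79 named genes 74 kept their direction in every setting run for genes, and 0 passed the limma threshold there. The other ways to choose a probe set were run for lists only, and 15 named genes have probe sets that differ in direction. With an estimated correlation or fry the count of lists moved from 17 to 0. The angiogenesis (-0.16), morphogenesis (-0.14) and cytokine (0.66) differences stayed as they were. Their values were adjusted p = 0.463 with an estimated correlation and limma fry adjusted p = 0.0908, 0.309 and 0.267. The correlations estimated for these 3 lists were 0.062, 0.14 and 0.31, above the preset 0.01. The p-values of camera at the preset thus assume more independence between genes than was estimated. The cause of the change with fry was not tested. The morphogenesis difference was -0.084 with the 3'/5' covariate (limma camera adjusted p = 0.0709) and ranged from -0.18 to -0.085 with a fetus left out, and its call ended without saline replicate 2; its limma camera adjusted p was 6.38e-04 to 0.0813 over these fits, and the cause was not tested. The count of 269 probe sets at an unadjusted p under 0.01 and at least 1.5-fold ranged from 159 (without GBS replicate 4) to 608 (without saline replicate 4); the cause was not tested.

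Values near 0 changed sign in some settings, and the cause was not tested. The glucocorticoid list was 0.014 with the filter on dim genes, 0.019 after quantile normalisation, 0.033 with array weights and 0.039 with the deviation removed, and -0.096 to 0.087 with a fetus left out. SFTPB was -0.024 with arrays centred, -0.0028 with the deviation removed and -0.060 to 0.046 with a fetus left out. TNF was -0.019 with arrays centred, -0.023 after quantile normalisation, -0.032 with the deviation removed and -0.043 to 0.046 with a fetus left out. The oxidative phosphorylation list was -1.77e-04 with arrays centred, -0.0077 with the 3'/5' covariate and -0.0016 to 0.042 with a fetus left out. With the 3'/5' covariate NKX2-1 was 0.0033, SFTPC -0.052 and the mesothelium list -0.056. With a fetus left out SFTPC ranged from -0.069 to 0.14, FOXF1 from -0.44 to 0.057, the mesothelium list from -0.078 to 0.12, ciliated cells from -0.15 to 0.37, secretory and basal cells from -0.083 to 0.49, neuroendocrine cells from -0.0080 to 0.15 and cartilage from -0.061 to 0.17; the last 4 were below 0 only without GBS replicate 1. Among lists that were not called, type I cells ranged from -0.28 to -0.14 with a fetus left out, lymphatic endothelium from 0.033 to 0.15, B cells from 0.027 to 0.21, platelets from -0.15 to -0.047, mast cells from 0.18 to 0.69, thymus from 0.064 to 0.13, cardiac and skeletal muscle from -0.14 to -0.032, liver from 0.025 to 0.081, immediate early genes from 0.086 to 0.27, retinoid handling from -0.068 to -0.015, and lung fluid and ion transport from -0.088 to -0.013; the cause was not tested. A covariate from Y-linked genes, fixed beforehand, was not run, since 0 genes of its list were measured. Dim genes such as KDR and TNF, with signal near the low end of the array, limit what their differences show. No paired analysis was possible because the labels give no numbers shared between the groups.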

Other observations

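The genes below were noticed after the data were seen; the lists for fatty acid oxidation and lipid-handling macrophages were written before their other members were examined, and the tests of intensity-dependent deviation were chosen only after the result was seen.

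Zinc finger genes, a large family of transcription factors that includes many repressors, were lower in GBS for 230 of 307 measured members, by -0.12 on average (SE 0.036, n = 5 and 5; exact permutation p = 0.0159). Replication-dependent histone genes were higher for 29 of 33, by 0.17 (SE 0.058; exact permutation p = 0.0238, limma camera p = 0.0279 with an estimated correlation). Both families were picked after the data were seen, and no members were held out. Their p-values therefore describe a pattern already chosen and are no independent test of it. For the zinc finger genes the difference was -0.10 with intensity-dependent deviation removed (exact permutation p = 0.0238), so the removal took away only part of it. With the control 3'/5' ratio as a covariate it was -0.096 (SE 0.036), and the limma camera p with an estimated correlation rose from 0.0478 to 0.0654 as the difference shrank and a degree of freedom was lost. The shift cleared the bound set beforehand by no more than about its SE, so a difference in RNA integrity cannot be told apart from other causes here. A change in cell mixture may contribute and was not tested. More dividing cells were considered for the histone genes: over the 10 fetuses their mean correlated with the cell division list at r = 0.20 (permutation p = 0.578) and rho = 0.37 (permutation p = 0.297). Without GBS replicate 4 and saline replicate 2, the 2 fetuses farthest from the median of the cell division list, r was 0.89. These 2 were also the highest on that list, at 6.24 and 6.22, while saline replicate 3, at 5.35, was kept. No p was computed for this r, and the fetuses were dropped for their values, so it is no evidence of a relation. Dividing cells cannot be told apart from other causes here.

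CPT1A and HADHA, which act in mitochondrial fatty acid oxidation, were both lower in GBS without overlap of the groups, HADHA by -0.34 (SE 0.073). The hypothesis that genes of this pathway were lower together was tested on the 13 other genes measured of a list. Their mean was lower by -0.11 (SE 0.035), with 9 of 13 lower and 5 of 5 GBS fetuses below every saline fetus (exact permutation p = 0.00794, the smallest possible), while the limma camera p with an estimated correlation was 0.0590. With intensity-dependent deviation removed the difference was -0.063 (exact permutation p = 0.0794), so part of it may come from the lean of bright genes toward saline.

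CH25H and FABP4, which handle sterols and lipids, and the phosphodiesterase SMPDL3A were among the 10 named genes with the largest higher values. These genes are expressed in macrophages. A role of SMPDL3A in lipid handling was not tested. The hypothesis that lipid-handling macrophage genes were higher together was tested on 15 other genes. Their mean was 0.28 higher (SE 0.12) with 12 of 15 higher, at an exact permutation p of 0.0556 and a limma camera p of 0.123 with an estimated correlation, and 4 of 5 GBS fetuses lay above every saline fetus. Of the 15, 2 stand on the fixed macrophage list, which was itself higher, so a rise specific to lipid handling cannot be told apart from more macrophage RNA.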
